A study of Homo sapiens with 24 samples.

How the data were processed

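The samples were cultures of SH-SY5Y, a neuroblastoma cell line with neuronal features, transfected with the expression plasmid pCAGIG. The plasmid was empty (Mock), or carried the 5' untranslated region of FMR1 with 21 CGG repeats (V21) or with 79 CGG repeats (V79). A further group, V79_8x, is described in the labels as overexpressing the 79-repeat region and carries the mark 8x. What the mark refers to is not given in the sources used here. The array names carry V80 where the labels say V79, and V80x2 where they say V79 8x. The labels were followed, so both the repeat number and the size of any excess rest on them alone. RNA was taken 24 h after transfection, and 100 ng of it was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. The design text gives 6 biological replicates for each of the 4 groups. Each array carries an experiment letter, B to G, which names it here (Mock D is the Mock array of experiment D).

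The values used are the authors' deposited table of log2 intensities, with 62976 features on each of 24 arrays. Scanner files, background signals and detection flags were not used here, so the size of a fold is uncertain where a group lies near the dim end of the array. The background correction and normalisation are not given in the sources used here, and the array names per the labels begin with IntNorm. The sorted values of the 24 arrays differed by at most 0.01, so the deposited values had been made equal in distribution between arrays before deposit. All array medians were 6.7. A fold below is a fold of these deposited intensities. For arrays, the number of replicates limits the precision: the median standard error of a log2 difference between groups was 0.098. As the arrays had been made equal in distribution, a shift of most genes in 1 direction would not be seen.

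Features were named through the platform annotation, brought up to date by transcript accession (33705 features) or by former symbol (644 features), and 2702 features kept the platform's symbol. In all, 37051 features had 1 gene, 0 had several and 25925 had none in that annotation. Of 20061 genes, 7156 had more than 1 feature. The brightest feature by the mean over the 24 arrays stood for the gene, and other features of a named gene are given where they disagreed. The dimmest 25% of genes were left out (mean below 6.43), which left 15045 genes for testing.

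Differences were tested with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0 for random blocks) in R 4.3.3. The 4 groups entered 1 fit with no covariates, and each p was two-sided and adjusted by Benjamini-Hochberg over the 15045 genes of a comparison, with a threshold of 0.05. "Rose" and "fell" refer to genes or lists past that threshold. The ± after a log2 difference is its standard error, and the ± after a level is the SD over 6 arrays. All 6 comparisons between the 4 groups were made. The groups recur among them, so counts of different comparisons are not independent of each other.

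Gene lists were written before the data were examined, as were the main design and the alternatives except where stated. There were 26: interferon response, integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock response, p53 targets, immediate early genes, NF-kB targets, G2/M phase, S phase, proteins described with CGG repeat RNA, the FMRP family, neurodegeneration genes, ovarian insufficiency genes, noradrenergic neuronal genes, mesenchymal genes, glial genes, oxidative phosphorylation, cholesterol synthesis, hypoxia and glycolysis, NRF2 targets, metal response, ribosomal proteins, proteasome, histones, splicing factors and synaptic receptors. The mesenchymal and glial lists hold markers of other cell types. The lists hold 755 distinct genes, of which 666 were tested, and 31 had no named feature and were not analysed here. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. The mean of each list was also compared by an exact permutation of the 12 arrays, adjusted over the 26 lists, which does not compare them with other genes either.

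Named genes followed a fixed rule. For V79 against V21, V79_8x against V79, V21 against Mock and V79_8x against Mock it took up to 10 genes with the largest rise and 10 with the largest fall, and for the remaining 2 comparisons up to 5 and 5. These had to pass the threshold and move the same way in at least 5 of 6 experiments. A count of experiments given for a gene named this way is therefore no separate support. Where none passed, the rule took the 3 smallest p-values. It added FMR1, and per list up to 4 members past the threshold with the largest change, or up to 2 with the smallest p where none passed. A gene taken from outside this rule is said to be so.

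The procedure was tested on simulated data for V79_8x against Mock over 15045 genes, with 50 genes changed at each of 4 sizes. It recovered 10% of changes of 0.25 on the log2 scale, 76% at 0.5, 96% at 1 and 98% at 2, and 10 of its 150 calls were false. In the unchanged comparison of V21 with Mock of that simulation it made 0 calls. The simulated noise was independent between genes and held no arrays that stand apart. These rates therefore do not cover such structure in the real arrays, where another split of the V21 and Mock arrays gave up to 2668 calls.

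Alternatives covered normalisation (quantile again, 75th percentile), the filter on dim genes (none, or the lowest 50%), the treatment of several features per gene, the spread (trended and robust, only the 2 groups compared), the experiment letter as a block, the first number of the array name as a term, array weights, a minimum log2 change of 0.5, and each array left out in turn. After the data were seen, 4 arrays were found to stand apart (Mock D, V21 B, V21 C and V79 B): their median correlations with the other arrays were 0.973 to 0.98, against 0.991 to 0.995 for the other 20. Leaving these 4 out was therefore added as an alternative chosen after seeing the data. No pair of arrays held identical values.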

Results

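Expression was measured in SH-SY5Y neuroblastoma cells 24 h after transfection with the empty vector (Mock), with the FMR1 5' untranslated region carrying 21 or 79 CGG repeats (V21, V79), or with the 79-repeat region in the condition marked as overexpressing (V79_8x). FMR1 encodes FMRP, an RNA-binding protein of neurons, and expanded CGG repeats in this region are carried in the fragile X premutation. Each group had 6 arrays, and 15045 genes were tested. The comparisons ask what the transcribed region changes against the vector, what the longer repeat changes against the shorter, and what the 8x condition changes against the same repeat without it.

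FMR1 itself did not differ between groups. Its level was 9.91 ± 0.20 in Mock, 9.93 ± 0.19 in V21, 9.81 ± 0.37 in V79 and 9.87 ± 0.26 in V79_8x (log2, SD, n = 6). Its dimmer feature lay at 7.97, 7.88, 8.07 and 8.16 in the same order. The position of these features against the plasmid's part of FMR1 is not given in the sources used here, and a probe outside that part reads the cell's own FMR1 and checks nothing about the plasmid. The FMRP family list did not pass in any comparison. Within it CYFIP2, which encodes a partner protein of FMRP, was the 1 of 9 genes past the threshold in V79_8x against V21 (+0.40 ± 0.11, adjusted p = 0.044), a call that was lost without any 1 of 16 arrays (adjusted p of up to 0.14, without V21 B).

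In cells with 79 repeats, SERPINA3 was higher than in cells with 21 repeats. SERPINA3 encodes the acute-phase protease inhibitor alpha-1-antichymotrypsin. Its level was 7.85 ± 0.13 in V79 and 7.29 ± 0.13 in V21, a difference of 0.56 ± 0.08 (adjusted p = 0.0045, higher in 6 of 6 experiments). ICAM1, a cell adhesion molecule of inflammation, came next at +0.47 ± 0.08 (adjusted p = 0.063) and did not pass. No other gene of 15045 was called, and 574 had an unadjusted p under 0.05 where 752 would be met by chance. Another of the 3 SERPINA3 features gave +0.56 (adjusted p = 0.0042) and the remaining one +0.13 (adjusted p = 0.97). In V79_8x, other cultures with 79 repeats, SERPINA3 lay at 8.15 ± 0.13, above V21 by 0.86 and above Mock by 0.88 (adjusted p = 3.7e-08 and 2.2e-08). Against V79 it was at +0.30 there (adjusted p = 0.085), while the second of its features gave +0.47 (adjusted p = 0.00047). Without the 4 arrays that stand apart SERPINA3 differed by 0.48 ± 0.09 (adjusted p = 0.28), and with only the 2 groups in the fit its adjusted p was 0.15. The count was 2 genes without V21 D and 2 without V79_8x B.

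Of the lists, 5 passed with the preset correlation in V79 against V21, and 0 with an estimated correlation, with fry or with the exact permutation of list means. Interferon-response genes leaned up, with 0 of 40 genes past the threshold, 1 adjusted over the list alone, and a median of +0.09 (adjusted p = 0.00029, and adjusted p = 0.69 with an estimated correlation). The p53 targets had a median of +0.13 with 0 of 26 genes past the threshold and 0 adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.37 with an estimated correlation). The means of these 2 lists were higher in V79 in 6 of 6 experiments, by 0.15 and 0.12 (exact permutation adjusted p = 0.281 and 0.31). The interferon mean of V79 (8.60) was near that of Mock (8.59), and V21 lay lower (8.45). NF-kB targets had a median of +0.10 with 0 of 14 genes past the threshold and 2 adjusted over the list alone (adjusted p = 0.00056, and adjusted p = 0.44 with an estimated correlation). Glial genes had a median of +0.13 with 0 of 6 past the threshold and 0 adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.44 with an estimated correlation). Among the 29 histone genes, 26 had a lower value in V79 and 0 passed (0 adjusted over the list alone), with a median of -0.25 (adjusted p = 8.7e-09, and adjusted p = 0.44 with an estimated correlation). Histone genes were also the group by which the 4 arrays stood apart: their median shift from the group was 0.70 on V21 B, 1.05 on V21 C, 0.50 on Mock D and 0.38 on V79 B, and at most 0.14 on the other 20. Without these 4 arrays the histone list had an adjusted p of 0.11, while the interferon, p53 and NF-kB lists had 1.1e-05, 1.9e-05 and 2.9e-05 with the preset correlation, and did not pass with an estimated one (adjusted p = 0.54, adjusted p = 0.11 and adjusted p = 0.13 with an estimated correlation). The difference of the glial list means went from 0.14 to 0.09 there. Proteins described with CGG repeat RNA, uncalled with all arrays (adjusted p = 0.055), leaned down without the 4 (difference of list means -0.04, adjusted p = 0.0033, and adjusted p = 0.044 with an estimated correlation).

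**Figure D1:**
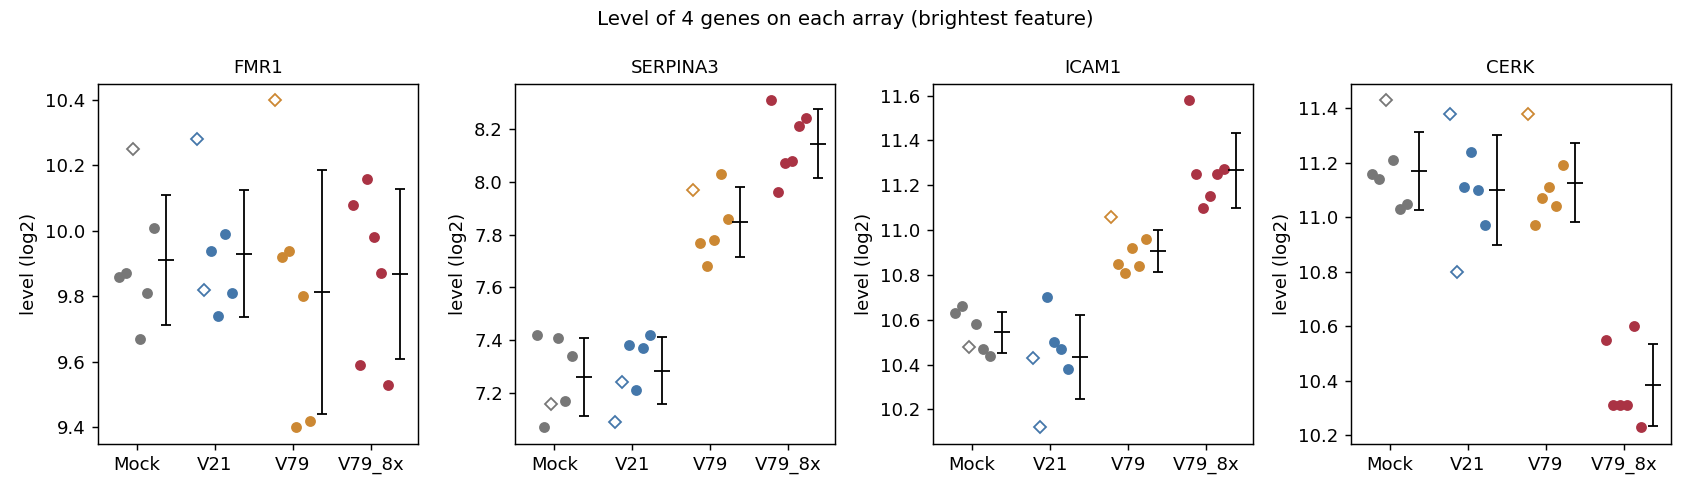
Level of named genes on each array (log2 intensity, y axis) in Mock, V21, V79 and V79_8x (x axis). Filled circles are arrays in the order of their experiment letters, open diamonds are the 4 arrays that stand apart, and black bars give the mean ± SD of 6 arrays. SERPINA3 lies at 7.26 in Mock, 7.29 in V21, 7.85 in V79 and 8.15 in V79_8x, and FMR1 between 9.81 and 9.93.

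Cells of the V79_8x group carried a broad rise of interferon-stimulated genes against cells with the same repeat without the 8x mark. IFI44L went from 6.92 ± 0.59 to 12.04 ± 0.36, a 34.7-fold rise (log2 +5.12 ± 0.24, adjusted p = 9.9e-14). IFIT1, which binds foreign RNA, rose 31.7-fold, the membrane restriction factor IFITM1 26.2-fold, IFI27 21-fold, and IFIT3, a partner of IFIT1, 19.5-fold. ISG15, a ubiquitin-like modifier, rose 11.4-fold, from 11.57 to 15.08. Further large rises were those of OASL, MX2, IFI44 and IFI6 (log2 +3.87, +3.39, +3.30 and +3.12). Each of these 10 genes was higher in 6 of 6 experiments. MX2 lay at 6.42 in V79, below the limit of the filter, so the size of its rise is uncertain, and its other feature gave -0.09 (adjusted p = 1). IFI44L lay under that limit on V79 B and V79 C (6.31 and 6.42), which leaves the size of its fold uncertain as well.

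In total 173 genes changed in V79_8x against V79, of which 153 rose and 20 fell. Among the risers 63 rose more than 2-fold and 26 more than 4-fold, and the largest fall was that of CERK at -0.74. Of the 40 interferon-response genes tested, 38 rose and 0 fell (39 adjusted over the list alone), with a median of +1.98 (camera adjusted p = 3.4e-270, and adjusted p = 2.1e-09 with an estimated correlation). The list mean was 8.60 ± 0.09 in V79 and 10.81 ± 0.20 in V79_8x, and the 6 V79_8x arrays, from 10.54 to 11.01, all lay above the highest V79 array at 8.68. The exact permutation p of 0.00216 is the smallest that 6 against 6 arrays can give (adjusted p = 0.0141 over 26 lists). The 2 genes that did not pass were RIGI and LGALS3BP, named after their values were seen. RIGI encodes a cytosolic sensor of viral RNA. Its brightest feature was far up on Mock D, V21 B and V79 B and gave +1.23 (adjusted p = 0.98), and its other feature gave +2.55 (adjusted p = 2e-12). The total was 274 genes without the 4 arrays that stand apart.

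**Figure D2:**
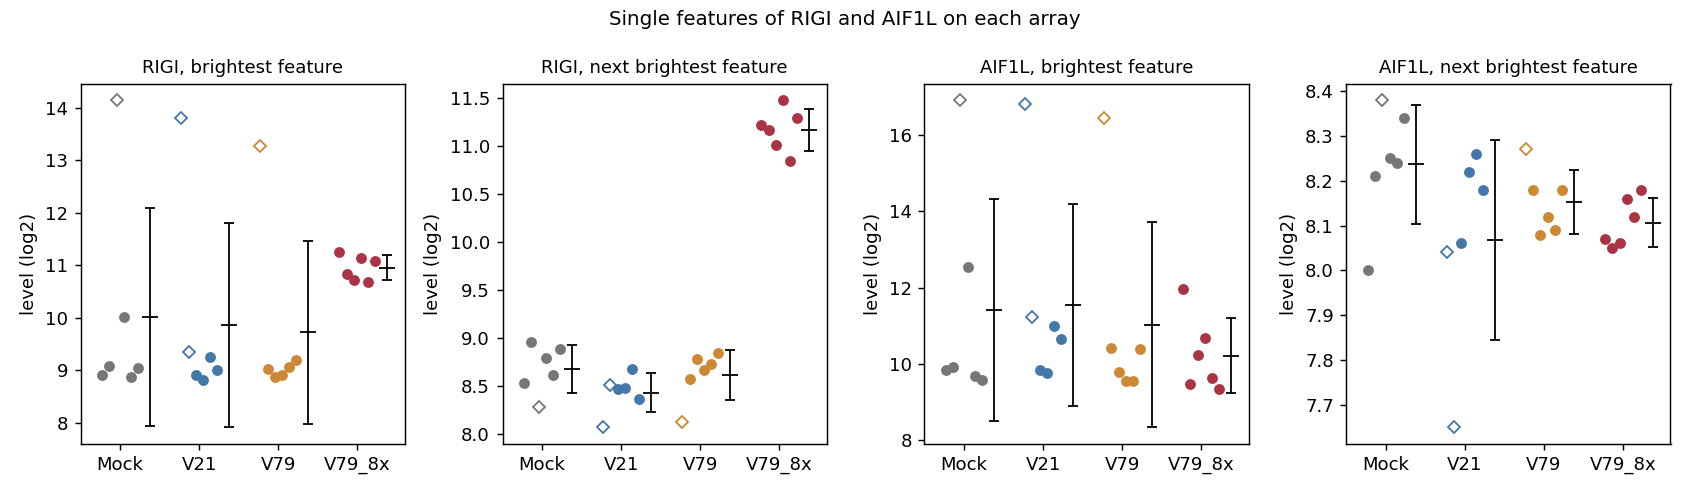
Level of the brightest and next brightest features of RIGI and AIF1L on each array (log2 intensity, y axis) in the 4 groups (x axis). Filled circles are arrays, open diamonds the 4 arrays that stand apart, and black bars the mean ± SD of 6 arrays. RIGI's brightest feature reads 14.15 on Mock D, 13.81 on V21 B and 13.27 on V79 B against a median of 9.08 on the other 20 arrays, and its next brightest feature reads 8.28, 8.07 and 8.12 there.

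Metallothioneins, small proteins that bind zinc and copper, also rose in V79_8x against V79. MT2A rose 1.99-fold (+0.99 ± 0.06, adjusted p = 2.4e-11), MT1L by +0.92, MT1B by +0.84 and MT1H by +0.83. Of 12 metal-response genes 8 rose and 0 fell (8 adjusted over the list alone), with a median of +0.71 (adjusted p = 1.3e-29, and adjusted p = 5.3e-05 with an estimated correlation). Metallothionein genes are close copies of each other, so their features can read each other's transcripts and single members are uncertain. Of 26 p53 targets 2 rose (6 adjusted over the list alone), with a median of +0.14 (adjusted p = 2.4e-07, and adjusted p = 0.023 with an estimated correlation). These included GDF15, a secreted stress cytokine, at +0.63 ± 0.10 (adjusted p = 0.00048), and SPATA18, a protein of mitochondrial quality control, at +0.41 (adjusted p = 0.022), lost without any 1 of 5 arrays (adjusted p of up to 0.079, without V79_8x E). Of 14 NF-kB targets 2 rose (3 adjusted over the list alone): BIRC3, an inhibitor of apoptosis, at +0.44 (adjusted p = 0.00054) and ICAM1 at +0.36 (adjusted p = 0.024). The NF-kB list's adjusted p was 0.00011, and adjusted p = 0.21 with an estimated correlation. The ICAM1 call was lost without V79 F, V79 C, V79 D, V79_8x B or V79_8x G (adjusted p = 0.07, 0.07, 0.076, 0.077 and 0.057).

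The lists of G2/M phase, S phase and cholesterol synthesis leaned down in V79_8x against V79 with the preset correlation, with 0 members past the threshold. None of the 3 passed the exact permutation of list means (adjusted p = 0.0774, 0.788 and 0.0819). In the G2/M list 29 of 31 genes had lower values, with 0 past the threshold and 5 adjusted over the list alone, and a median of -0.12 (adjusted p = 1.9e-10, and adjusted p = 0.088 with an estimated correlation). BIRC5 and MKI67, a marker of dividing cells, gave -0.21 and -0.34 (both adjusted p = 0.14). The S phase list had 0 of 27 genes past the threshold and 0 adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.61 with an estimated correlation), and its difference of list means went from -0.03 to -0.08 without the 4 arrays, of which V79 B is in this comparison. Cholesterol synthesis had 0 of 26 on either count (adjusted p = 0.0016, and adjusted p = 0.21 with an estimated correlation), led by DHCR7, the last enzyme of cholesterol synthesis, at -0.23 (adjusted p = 0.31). Of 29 histone genes 1 fell (1 fell and 1 rose adjusted over the list alone), with a median of -0.22 (adjusted p = 4.4e-06, and adjusted p = 0.44 with an estimated correlation), and V79 B had a histone shift of 0.38. The 1 gene was H4C3 at -0.29 (adjusted p = 0.033), lost without any 1 of 9 arrays (adjusted p of up to 0.11, without V79 F). Without the 4 arrays the histone list kept its direction (adjusted p = 7.5e-07, and adjusted p = 0.16 with an estimated correlation).

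A further 3 lists passed upward with the preset correlation, and with neither an estimated one nor fry. By the exact permutation of list means glial genes and NRF2 targets passed (adjusted p = 0.0188 and 0.0141) and neurodegeneration genes did not (adjusted p = 0.0813). Neurodegeneration genes had 1 of 26 genes up (2 adjusted over the list alone), OPTN, an autophagy receptor, at +0.28 ± 0.06 (list adjusted p = 0.015, and adjusted p = 0.52 with an estimated correlation), and their difference of list means went from 0.07 to 0.04 when V79 B and the other 3 arrays were left out. Glial genes had 1 of 6 up (1 adjusted over the list alone), CNP, an enzyme of myelin that the line also expresses at 15.14, at +0.42 ± 0.07 (list adjusted p = 0.012, and adjusted p = 0.27 with an estimated correlation). NRF2 targets had 0 of 21 on either count (list adjusted p = 0.043, and adjusted p = 0.21 with an estimated correlation), with NQO1 at +0.17 (adjusted p = 0.57). Of the 26 lists, 11 passed with the preset correlation, 3 did with an estimated one and with fry, and 6 by exact permutation, namely the interferon, metal, p53, glial, NRF2 and histone lists.

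Outside the lists, the largest falls in V79_8x against V79 were those of CERK, ceramide kinase, from 11.13 ± 0.14 to 10.38 ± 0.15 (adjusted p = 8.1e-06), and of NFYA, a subunit of the CCAAT-binding factor NF-Y, at -0.71 ± 0.11 (adjusted p = 0.00024). The other NFYA feature gave -0.09 (adjusted p = 1). PMEPA1, a transmembrane protein of TGF-beta signalling, fell by 0.45 ± 0.06 (adjusted p = 6.1e-06), and NT5DC2, MALL and NRGN by 0.46, 0.40 and 0.37. PRR11, a protein of the cell cycle, fell by 0.49 (adjusted p = 0.035), ACO1, an aconitase that also binds RNA, by 0.43 (adjusted p = 0.022), H4C13, a histone H4 gene, by 0.42 (adjusted p = 0.033) and MTURN by 0.39 (adjusted p = 0.012). These 4 calls depended on single arrays: PRR11's was lost without any 1 of 10 arrays (adjusted p of up to 0.12, without V79_8x E), ACO1's without any 1 of 7 (up to 0.077, without V79 G), H4C13's without any 1 of 7 (up to 0.11, without V79 C, V79_8x B or V79_8x C) and MTURN's without V79_8x G (adjusted p = 0.05). The other MTURN feature gave -0.14 (adjusted p = 1). Each of these 10 genes fell in 6 of 6 experiments. Of the 37 genes the rule named past the threshold, 26 were called whichever array was left out and 11 lost their call without at least 1 array.

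The remaining 15 lists did not pass in V79_8x against V79 (adjusted p from 0.092 to 0.99). In the integrated stress response 2 of 34 genes rose (3 adjusted over the list alone): NUPR1, a stress-induced chromatin protein, at +0.45 (adjusted p = 0.00067), and the glycine transporter SLC6A9 at +0.36 (adjusted p = 0.01), whose call was lost with the mean of all its features (adjusted p = 0.99). Of 32 immediate early genes 2 fell, EGR1 and ARC, both at -0.35 (adjusted p = 0.043 and 0.036), and these calls were lost without any 1 of 12 and 9 arrays, with adjusted p of up to 0.14 (without V79 F) and 0.097 (without V79 C). Of 16 ovarian insufficiency genes 1 rose, INHBA, which encodes a subunit of activin, at +0.37 (adjusted p = 0.026), lost without any 1 of 6 arrays (adjusted p of up to 0.092, without V79_8x G). Of 28 noradrenergic neuronal genes 1 fell, the neuropeptide VIP at -0.23 (adjusted p = 0.038), lost without any 1 of 12 arrays (adjusted p of up to 0.14, without V79 D). The mesenchymal list, markers of the other cell type of this line, had 0 of 26 and a median of -0.01. No member passed among 23 ER chaperone genes, 25 heat shock genes, 26 genes of proteins described with CGG repeat RNA, 43 of oxidative phosphorylation, 32 of hypoxia and glycolysis, 40 of ribosomal proteins, 31 of the proteasome, 30 of splicing or 17 synaptic receptor genes. Their medians lay between -0.02 and +0.03. For the ER, splicing and synaptic lists the median, the mean and the test differed in sign.

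**Figure D3:**
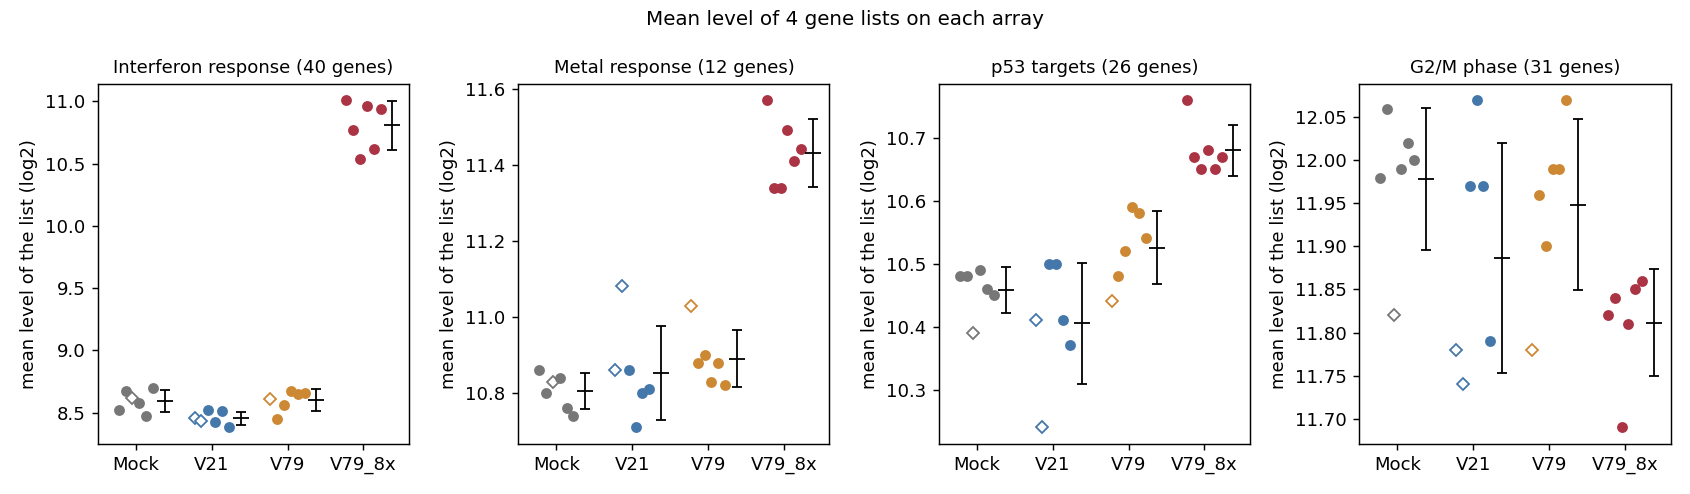
Mean log2 intensity of gene lists on each array (y axis) in Mock, V21, V79 and V79_8x (x axis). Filled circles are arrays in the order of their experiment letters, open diamonds are the 4 arrays that stand apart, and black bars give the mean ± SD of 6 arrays. The interferon list is at 10.81 in V79_8x and between 8.45 and 8.60 in the other groups, and the metal list at 11.43 against 10.80 to 10.89.

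Against the empty vector, V79_8x cells again had their largest rises among interferon-stimulated genes. IFITM1 rose 40.9-fold (log2 +5.35 ± 0.26, adjusted p = 1.9e-13), IFI44L 34-fold, IFI27 28.3-fold, IFIT1 26.1-fold and IFIT3 17.4-fold. BST2, which tethers enveloped viruses to the cell surface, rose 10.1-fold, from 8.31 ± 0.14 to 11.64 ± 0.21. In all 331 genes changed, of which 258 rose and 73 fell, with 63 rises above 2-fold and 1 fall beyond 2-fold. Of the 40 interferon-response genes 38 rose (39 adjusted over the list alone), with a median of +2 (adjusted p = 3.9e-215, and adjusted p = 1.7e-08 with an estimated correlation). The total was 597 without the 4 arrays that stand apart and 1045 with array weights.

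Of 12 metal-response genes 8 rose against Mock (10 adjusted over the list alone), with a median of +0.81 (adjusted p = 4.7e-29, and adjusted p = 6.1e-05 with an estimated correlation), and MT2A was at +1.07 ± 0.06. Of 26 p53 targets 6 rose (14 adjusted over the list alone), with a median of +0.22 (adjusted p = 7.1e-11, and adjusted p = 0.0036 with an estimated correlation). GDF15 rose by +0.89 ± 0.10 (adjusted p = 2.5e-06), BBC3, the pro-apoptotic protein PUMA, by +0.45 (adjusted p = 0.014), FDXR, a mitochondrial reductase, by +0.40 (adjusted p = 0.0017) and SPATA18 by +0.36 (adjusted p = 0.037), lost without any 1 of 8 arrays (adjusted p of up to 0.12, without Mock D). Of 14 NF-kB targets 3 rose (8 adjusted over the list alone), namely ICAM1 at +0.72, BIRC3 at +0.55 and TNFAIP2 at +0.38 (list adjusted p = 1.2e-09, and adjusted p = 0.034 with an estimated correlation). Neurodegeneration genes had 2 of 26 up (2 adjusted over the list alone), OPTN at +0.34 and GRN, which encodes progranulin, at +0.38 (list adjusted p = 0.0055, and adjusted p = 0.33 with an estimated correlation). Glial genes had CNP up, 1 of 6 on either count, at +0.48 (list adjusted p = 0.012, and adjusted p = 0.28 with an estimated correlation).

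Replication-dependent histone H4 genes were the leading falls against Mock. H4C11 fell by 1.15 ± 0.19 (adjusted p = 0.00053), from 15.38 ± 0.31 to 14.23 ± 0.37. Among H4 genes it was followed by H4C6, H4C8, H4C12, H4C9 and H4C15 at -0.94, -0.83, -0.81, -0.80 and -0.77. These genes are near-identical copies, so their features can read each other's transcripts and single members are uncertain. The values of V79 and V21 also lay below Mock, uncalled, for H4C11 (-0.60 and -0.50, adjusted p = 1 and 0.78) and H4C6 (-0.56 and -0.34, adjusted p = 0.83 and 0.78). None of these 6 genes was called in V79_8x against V79 (H4C11 at -0.55, adjusted p = 0.41, and H4C6 at -0.38, adjusted p = 0.39), so how much of the falls against Mock belongs to the 8x condition is not settled. Of the 29 genes in the histone list 2 fell and 0 rose (8 fell and 1 rose adjusted over the list alone), with a median of -0.26 (adjusted p = 1.2e-10, and adjusted p = 0.21 with an estimated correlation). Mock D, 1 of the 4 arrays, had a histone shift of 0.50, and without the 4 arrays H4C11 was at -1.08 (adjusted p = 9.2e-05) and the list had adjusted p = 0.049 with an estimated correlation. CERK fell by 0.79 ± 0.09 and NFYA by 0.72. MARK2, a microtubule affinity kinase, fell by 0.76 (adjusted p = 0.0036), while its other feature gave +0.06 (adjusted p = 1).

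Of 31 G2/M genes 3 fell against Mock (5 adjusted over the list alone), with a median of -0.16 and 30 of 31 values lower (adjusted p = 5.9e-13, and adjusted p = 0.034 with an estimated correlation). TTK, a kinase of the spindle checkpoint, was at -0.32 ± 0.07 (adjusted p = 0.0092). MKI67 at -0.43 and CCNA2, a cyclin of S and G2, at -0.27 (both adjusted p = 0.016) lost their calls without single arrays: MKI67 without Mock D, Mock G or V79_8x E (adjusted p = 0.054, 0.05 and 0.055), and CCNA2 without Mock D, Mock E or V79_8x D (adjusted p = 0.054, 0.051 and 0.054). S phase had 0 of 27 past the threshold on either count with a median of -0.08 (adjusted p = 0.00035, and adjusted p = 0.3 with an estimated correlation). With the 4 arrays left out, Mock D among them, its difference of list means went from -0.08 to -0.12 (adjusted p = 0.033 with an estimated correlation). Cholesterol synthesis had 0 of 26 on either count with a median of -0.10 (adjusted p = 3.4e-05, and adjusted p = 0.084 with an estimated correlation). Of the 26 lists 10 passed with the preset correlation, 5 with an estimated one, 8 with fry and 9 by exact permutation. The other 16 lists did not pass with the preset one (adjusted p from 0.091 to 0.91), NRF2 targets among them, which passed by exact permutation (adjusted p = 0.0161).

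Against 21 repeats, V79_8x cells showed the same kind of leading genes, with IFITM1 up 56.6-fold (log2 +5.82 ± 0.26, adjusted p = 2.9e-14), IFI44L 47.2-fold, IFIT1 45.6-fold, IFI27 37-fold and IFIT3 24.7-fold. The levels of IFI44L and IFIT3 in V21, 6.48 and 6.44, lay at the filter's limit of 6.43, so the size of these 2 folds is uncertain. There were 431 changed genes, of which 329 rose and 102 fell. Of 40 interferon-response genes 38 rose (38 adjusted over the list alone), with a median of +2.06 (adjusted p = 1.4e-134, and adjusted p = 9.2e-07 with an estimated correlation). The total was 728 without V21 E and 243 with only the 2 groups in the fit. Of the 26 lists 10 passed with the preset correlation, 3 with an estimated one, 9 with fry and 8 by exact permutation. The other 16 had adjusted p from 0.053 to 0.91 with the preset one, and 2 of them, neurodegeneration genes and NRF2 targets, passed by exact permutation (adjusted p = 0.0281 and 0.00804).

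Of 26 p53 targets 9 rose against V21 (15 adjusted over the list alone), with a median of +0.28 (adjusted p = 3e-09, and adjusted p = 0.0081 with an estimated correlation), GDF15 being at +0.77 ± 0.10. BBC3 and the stress protein TP53INP1 were at +0.43 and +0.62 (adjusted p = 0.018 and 0.015), and both calls were lost without V21 B (adjusted p = 0.062 and 0.054). Metal-response genes had 8 of 12 up (9 adjusted over the list alone; adjusted p = 5.7e-16, and adjusted p = 0.0025 with an estimated correlation). NF-kB targets had 3 of 14 up (6 adjusted over the list alone), with ICAM1 at +0.83 and TNFAIP2 at +0.45 (list adjusted p = 4.3e-06, and adjusted p = 0.17 with an estimated correlation). Glial genes had 2 of 6 up (3 adjusted over the list alone), CNP at +0.52 and the neurotrophin receptor NGFR at +0.47 (list adjusted p = 0.0011, and adjusted p = 0.17 with an estimated correlation). In the integrated stress response 3 of 34 genes rose and 1 fell (6 and 1 adjusted over the list alone), with NUPR1 at +0.53 and the tRNA exporter XPOT at -0.32 (list adjusted p = 0.033, and adjusted p = 0.57 with an estimated correlation). V21 B and V21 C, 2 of the arrays that stand apart, had the lowest means of this list in V21 (10.24 and 10.14, the other 4 from 10.33 to 10.49). With the arrays that stand apart left out the difference of list means went from 0.14 to 0.06 and the list was not called (adjusted p = 0.12), and by exact permutation it did not pass (adjusted p = 0.106). Without them the NF-kB and glial lists passed with an estimated correlation too (adjusted p = 0.019 and 0.044).

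Falls against V21 were led by H1-5, H3C2, CERK, TACC3 and SBDS at -0.89, -0.74, -0.72, -0.71 and -0.70. Those of H1-5, TACC3 and SBDS lost their calls without the 4 arrays (adjusted p = 0.17, 0.21 and 0.08) and without any 1 of 17, 8 and 7 arrays (adjusted p of up to 0.13, 0.11 and 0.09, each without V21 B). The other SBDS feature gave -0.03 (adjusted p = 0.92). Of 29 histone genes 5 fell and 1 rose (21 fell and 1 rose adjusted over the list alone), with a median of -0.45 (adjusted p = 6.7e-12, and adjusted p = 0.18 with an estimated correlation), V21 B and V21 C having histone shifts of 0.70 and 1.05. Without the 4 arrays H3C2 was at -0.44 (adjusted p = 0.0061), and the histone list's difference of means went from -0.41 to -0.17 (adjusted p = 0.1 with an estimated correlation). Of 31 G2/M genes 2 fell (5 adjusted over the list alone), MKI67 and CCNA2 (list adjusted p = 0.00051, and adjusted p = 0.44 with an estimated correlation), MKI67's call being lost without V79_8x E (adjusted p = 0.054) and CCNA2's without any 1 of 8 arrays (adjusted p of up to 0.098, without V21 B). S phase and cholesterol synthesis, with 0 of 27 and 0 of 26 on either count, had adjusted p of 0.02 and 0.019 (adjusted p = 0.57 and adjusted p = 0.44 with an estimated correlation). V21 B and V21 C had S phase means of 11.89 and 11.8, below the other V21 arrays (12.03 to 12.16). Leaving out the 4 arrays moved the difference of list means from -0.02 to -0.11 for S phase (adjusted p = 0.023 with an estimated correlation) and from -0.08 to -0.14 for G2/M (adjusted p = 0.089 with an estimated correlation).

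Between cells with 21 repeats and cells with the empty vector, limma called 0 of 15045 genes. An unadjusted p under 0.05 was met by 486 genes, where 752 would be met by chance. Each of the other limma settings tried also gave 0. This does not show that the groups were alike. The simulation for V79_8x against Mock recovered only 10% of log2 changes of 0.25. Mock D, V21 B and V21 C, which stand apart, are in this comparison. The smallest p-values were those of OASL, an interferon-induced member of the oligoadenylate synthetase family (-0.65 ± 0.18), TTI2, a cofactor of PI3K-related kinases (-0.35 ± 0.10), and LRRC70 (-0.32 ± 0.09), all with an adjusted p of 0.78. Of the lists 3 passed with the preset correlation and 0 with an estimated one, fry or exact permutation. Interferon-response genes had lower values in 33 of 40 with 0 past the threshold (0 adjusted over the list alone) and a median of -0.08 (adjusted p = 0.0027, and adjusted p = 0.96 with an estimated correlation). G2/M genes had a median of -0.07 with 0 of 31 on either count (adjusted p = 0.011, and adjusted p = 0.96 with an estimated correlation), and their difference of list means went from -0.09 to -0.06 without Mock D, V21 B, V21 C and V79 B. Histone genes had a median of +0.14 with 0 of 29 on either count (adjusted p = 0.016, and adjusted p = 0.96 with an estimated correlation), and without the 4 arrays, with histone shifts of 0.50, 0.70 and 1.05 on Mock D, V21 B and V21 C, the list's direction turned downward (adjusted p = 0.016, and adjusted p = 0.83 with an estimated correlation). The other 23 lists did not pass (adjusted p from 0.1 to 0.95).

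In cells with 79 repeats, SERPINA3 was also higher than with the empty vector, at 7.85 ± 0.13 against 7.26 ± 0.15 (+0.59 ± 0.08, adjusted p = 0.0023, higher in 6 of 6 experiments). It was the 1 gene called of 15045, with 406 at an unadjusted p under 0.05 where 752 would be met by chance. With only the 2 groups in the fit its adjusted p was 0.098, and without the 4 arrays the difference was 0.54 (adjusted p = 0.025). ISL1, a transcription factor of sympathetic neurons, gave -0.27 and ICAM1 +0.36 (both adjusted p = 0.83). Of the lists 6 passed with the preset correlation and 0 with an estimated one, fry or exact permutation, and 0 members of them passed among all genes. NF-kB targets, p53 targets and metal-response genes leaned up by medians of +0.11, +0.08 and +0.09 (adjusted p = 6.1e-05, 0.0062 and 0.002, and each adjusted p = 0.38 with an estimated correlation), with 1, 0 and 0 genes adjusted over the list alone. Heat shock genes, proteins described with CGG repeat RNA and histones leaned down by medians of -0.06, -0.04 and -0.08 (adjusted p = 0.035, 0.032 and 0.002, and adjusted p = 0.79, 0.38 and 0.79 with an estimated correlation), with 0 genes each adjusted over the list alone, Mock D and V79 B having histone shifts of 0.50 and 0.38. The heat shock list had an adjusted p of 0.26 when the 4 arrays were left out. The interferon list did not pass (adjusted p = 0.79), and its median of -0.01 and mean of +0.01 differed in sign.

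**Figure D4:**
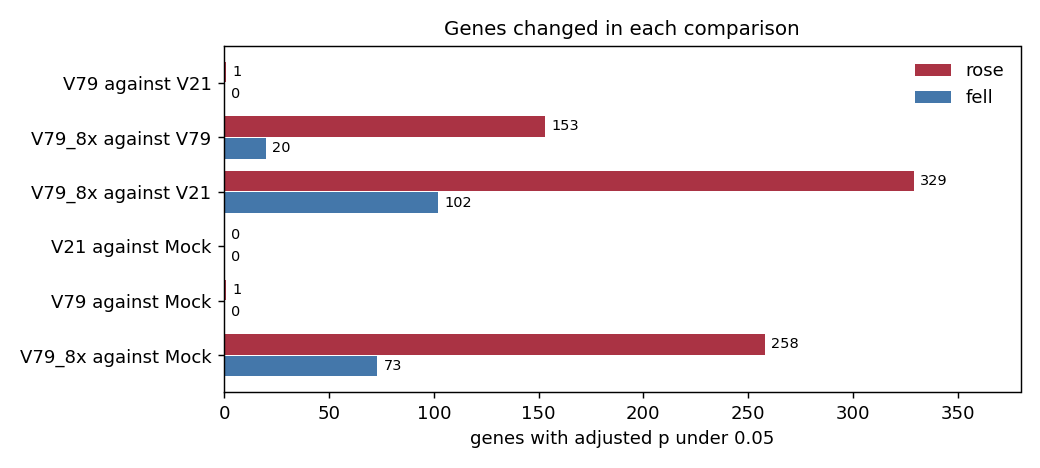
Number of genes that rose and fell (x axis, genes past an adjusted p of 0.05 of 15045 tested) in each of the 6 comparisons (y axis). V79_8x against Mock, V21 and V79 gave 258, 329 and 153 rises, and the comparisons among Mock, V21 and V79 gave 0 or 1.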

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

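The tests on the 4 arrays, on the interferon-response genes and on SERPINA3 in this part were chosen after those results were seen, and the counts of other splits of the samples were chosen before theirs.

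Single arrays lay far from the other 5 of their group in 49 of 408 groups of values (Dixon's test on 26 list means and 76 genes in 4 groups), where chance gives about 1 in 20 groups, or 20.4. Of the 49, 38 were on the 4 arrays that stand apart: 16 on Mock D, 15 on V79 B, 5 on V21 C and 2 on V21 B.

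Among list means, Mock D was lowest for the integrated stress response (10.26), NF-kB targets (9.419), G2/M phase (11.82), S phase (11.88), neurodegeneration genes (11.56), glial genes (10.26), oxidative phosphorylation (13.73), hypoxia and glycolysis (11.55) and ribosomal proteins (16.64), and highest for synaptic receptors (7.901). V79 B was lowest for heat shock (11.9), S phase (11.81), neurodegeneration genes (11.56), oxidative phosphorylation (13.69), NRF2 targets (11.01), ribosomal proteins (16.63), the proteasome (13.49) and splicing factors (11.84), and highest for metal response (11.03) and synaptic receptors (7.822). V21 B was highest for synaptic receptors (7.892). V79_8x B was highest for p53 targets (10.76) and mesenchymal genes (11.51), and V79_8x D lowest for G2/M phase (11.69). Protein-coding genes as a whole also lay lower on the 4 arrays that stand apart. Their median shift from the group (13934 genes) was -0.14 on Mock D, -0.11 on V21 B, -0.07 on V21 C and -0.11 on V79 B. The lowest of the other 20 arrays was V21 G at -0.0475. Low list means on the 4 arrays, here and above, may be part of this general shift, which was not separated.

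Among genes, Mock D was far from its group for NFYA (9.77), PRR11 (12.4), BIRC3 (7.52), OPTN (9.51), TP53INP1 (8.93) and FAS (7.84). V79 B was so for XPOT (10.21), TP53INP1 (9.12), EGR3 (6.29), MARK2 (10.29) and JDP2 (11.91). V21 C was so for OASL (6.3), MTURN (10.78), NUPR1 (7.58), MT1L (12.66) and JDP2 (11.85), and V21 B for PRR11 (12.44). On other arrays the values were MT1L on Mock B (12.33), LRRC70 on V21 D (6.14), SRSF3 on V79 D (14.68), ARC on V79 G (8.78), ICAM1 and JDP2 on V79_8x B (11.58 and 11.95), TACC3 on V79_8x E (10.6) and BBC3 on V79_8x F (12.01).

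Features without a gene in the annotation, which the comparisons did not use, also moved. Of 25925 such features 27 rose and 3 fell in V79_8x against V79, 66 rose and 10 fell against V21, and 54 rose and 7 fell against Mock, while limma called 0 in V79 against V21, V21 against Mock and V79 against Mock (689, 813 and 448 at an unadjusted p under 0.05). The 54 had median levels of 9.47, 9.52, 9.47 and 11 in Mock, V21, V79 and V79_8x, and rose by 0.24 to 2.06 (median 0.54).

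The 4 arrays Mock D, V21 B, V21 C and V79 B stood apart with histone genes up by 0.38 to 1.05. On each of Mock D, V21 B and V79 B, 151 features lay more than 2 (log2) above the median of the 20 arrays that do not stand apart. On V21 C the same features were up by a median of 0.775. Of the 151, 47 were the brightest feature of a gene, and these 47 were up by a median of 2.57 on the 3 arrays. For 25 of their genes there were 49 other features, up by a median of 0.03. This argues against higher expression of those 25 genes as a whole, though 2 of the 49 were up by more than 1. More of every RNA without a poly(A) tail is argued against as the whole cause by small nucleolar RNA genes, which were at -0.10 on V79 B, under the highest of the other 20 arrays (0.13), although they reached 0.80 on V21 C. A difference in RNA or hybridisation of these arrays stays open, and for the histone genes no biological explanation was tested.

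The rise of interferon-response genes in V79_8x against V79 was looked at further. With the experiment letter and the first number of the array name as terms, 38 of 40 genes still rose. Letters and numbers are spread equally over the groups, so these terms could not change a difference, only its spread. An effect of either that is alike in all groups cancels in the comparison, and the count adds no test of it. Without the 4 arrays 40 of 40 rose, which argues against those arrays as the whole cause. Both groups carry 79 repeats per the labels, so repeat length by itself does not account for the difference between them. The rise may come from the larger amount that the 8x label may stand for, whatever the repeat length. As 0 arrays carry 21 repeats with the 8x label, whether the rise needs the longer repeat cannot be told. A difference in the plasmid preparation or in the transfection of the V79_8x group was not tested and stays open.

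For SERPINA3 in V79 against V21, a single misreading feature is argued against by another feature at +0.562 (adjusted p = 0.0042), though the third was at +0.13 (adjusted p = 0.97). Without the 4 arrays the difference went from 0.56 ± 0.08 to 0.479 ± 0.09, which argues against these arrays as the whole cause, but the call ended (adjusted p = 0.28) with a smaller difference and fewer arrays. Over the alternatives its adjusted p ranged from 0.002 to 0.28. In V79_8x, other cultures with 79 repeats, SERPINA3 was also above V21 (+0.86, adjusted p = 3.7e-08), which a fault limited to the V79 cultures would not give unless the 8x condition raises it by itself. A difference between the plasmids was not tested, and repeat length stays open.

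Other splits of the 12 arrays of each comparison into 6 and 6 were drawn, 100 of the 462 possible, the real one included. As many genes as the real 173, 431 and 331 in V79_8x against V79, V21 and Mock came in 1, 1 and 1 of the 100 splits (highest other 60, 53 and 57), so chance can be excluded for these counts. As many as the real 1 in V79 against Mock came in 1, the real split (highest other 0). A contrast of 1 gene with 0 does not exclude chance firmly for a single call. As many as the real 1 in V79 against V21 came in 4 (highest other 4270), too close to the bound of 5 to exclude chance firmly from 100 drawn splits, and a count of 4270 points to a structure of the samples. With only the 2 groups compared both counts were 0, and without the 4 arrays that of V79 against V21 was 0. For the real 0 in V21 against Mock all 100 splits gave as many (highest other 2668). In each of these 2 comparisons 3 splits gave more than 10 genes, and all 3 put the arrays that stand apart on 1 side. Of the 100 splits 17 in V79 against V21 and 23 in V21 against Mock did so, most of them with no more than 10 genes, so that placing alone does not give a high count.

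For gene lists, as many as the real 11 in V79_8x against V79 came in 2 of 100 splits (highest other 11), under the bound of 5. As another split also gave 11, chance is not firmly excluded for that count. Chance cannot be excluded for the count in V79_8x against V21 (5 splits, real 10, highest other 11) or Mock (11 splits, real 10, highest other 11). Nor can it be for V79 against V21 (10 splits, real 5, highest other 9), V21 against Mock (22 splits, real 3, highest other 7) or V79 against Mock (7 splits, real 6, highest other 8). These are counts of lists and do not bear on single lists. The interferon list had an exact permutation p of 0.00216 in V79_8x against V79, V21 and Mock alike.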

How the results depend on the processing

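Leaving out the 4 arrays that stand apart, and each test of lists without them, was chosen after the data were seen, and the other alternatives here were chosen before. Quantile normalisation again and a 75th percentile shift changed no value, since the arrays were already equal, so they say nothing about stability. Of the 371 results for named genes and comparisons 130 were called. No alternative reversed a called one, and the direction was kept by all that could be tested. Among these settings only the mean of all probes, array weights and leaving out the 4 arrays could move a called difference. The others leave the difference of group means as it is, so a kept direction there says nothing about stability. The lowest 50% filter left 107 of the 130. Calls lost and gained were 26 and 2 with only the 2 groups compared, 11 and 12 without the 4 arrays, 8 and 25 with array weights, 9 and 3 with the mean of all probes, 6 and 0 with no filter on dim genes, 4 and 0 with the array name number as a term, and 0 and 1 with the trended and robust spread. In V79 against V21 the 1 gene became 0 with the lowest 50% of genes left out, since SERPINA3 at a mean of 7.64 lies under that limit of 8.42. It became 2 with every probe on its own, since 2 SERPINA3 features passed, 0 with only the 2 groups compared and 0 without the 4 arrays. In V79 against Mock the 1 became 0 with the lowest 50% left out, 2 with every probe on its own, 0 with only the 2 groups compared and 3 with array weights. In V79_8x against V79 the 173 became 313 with every probe on its own, 461 with array weights, 274 without the 4 arrays (172 of them shared) and 107 with a log2 change of at least 0.5. In V79_8x against V21 the 431 became 698 with every probe on its own, 243 with only the 2 groups compared and 187 with a change of at least 0.5. In V79_8x against Mock the 331 became 567 with every probe on its own, 1045 with array weights, 597 without the 4 arrays (327 shared) and 144 with a change of at least 0.5. Every probe on its own tests more features, and a minimum change removes small ones by construction. For the other moves the cause was not tested. The weights of the 4 arrays were 0.1 to 0.18. Leaving out each array in turn gave 1 to 2 genes in V79 against V21, 147 to 212 in V79_8x against V79, 319 to 728 in V79_8x against V21, 0 to 0 in V21 against Mock, 1 to 1 in V79 against Mock and 258 to 406 in V79_8x against Mock. The 728 came without V21 E, and the 2 without V21 D and without V79_8x B. The lists called went, with an estimated correlation, from 5 to 0 in V79 against V21, 11 to 3 in V79_8x against V79, 10 to 3 in V79_8x against V21, 3 to 0 in V21 against Mock, 6 to 0 in V79 against Mock and 10 to 5 in V79_8x against Mock. With fry they were 0 in V79 against V21, 3 in V79_8x against V79, 0 in V21 against Mock and 0 in V79 against Mock, and without the 4 arrays 8 in V79 against V21. Leaving these out ended the call of histones in V79 against V21, of the integrated stress response in V79_8x against V21 and of heat shock in V79 against Mock. It gained, with the preset correlation, heat shock, S phase, metal response and CGG repeat RNA proteins in V79 against V21, immediate early genes in each V79_8x comparison, neurodegeneration genes and CGG repeat RNA proteins in V79_8x against V21, and glial genes in V21 against Mock. Of these gains only CGG repeat RNA proteins in V79 against V21 passed with an estimated correlation (adjusted p = 0.044, the others from 0.079 to 0.83). An estimated correlation above 0.01 widens a list's test by construction, and every list that lost its call with it had one. How much of each loss comes from that was not separated. CGG repeat RNA proteins in V79 against Mock went from an adjusted p of 0.032 to 0.38 with an estimated correlation of only 0.016. Lists were not tested with each array left out. Dim genes were limited by signal: MX2 lay below the filter's limit of 6.43 in 3 groups.

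The experiment letter was also entered as a replicate block. Of 36 pairs of arrays with the same letter 16 had a correlation above 0.1 after group means were removed, 4 arrays correlated best with an array of their own letter, and the consensus correlation was 0.08, so the letters were not taken to pair the arrays. The median correlation within a letter ran from -0.13 in D to 0.31 in B. The 4 arrays that stand apart took part in all these values, so a pairing is not excluded. With the replicate block as a fixed term, V79 against V21, V79_8x against V79, V79_8x against V21, V21 against Mock, V79 against Mock and V79_8x against Mock gave 1, 185, 537, 0, 1 and 349 genes and 6, 11, 10, 3, 6 and 10 lists. With the replicate block as a random term they gave 2, 189, 541, 0, 1 and 370, the 2 in V79 against V21 being SERPINA3 and ICAM1 (adjusted p = 0.038). Of named results 7 lost and 2 gained a call with the fixed block, and 0 and 2 with the random one. An exact test of list means with the groups swapped within letters, added after the results were seen, called 0 lists in every comparison, but its smallest p of 0.0312 can pass an adjustment over 26 lists only where most lists reach it.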

Other observations

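The 3 lists of the next paragraph were chosen after the values were seen. The test of rising genes in V79 was chosen after the gene lists of V79 against V21 had been seen but before its own result, and the falling genes, the values without the 4 arrays and the calls from 2 groups alone were added to it after.

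Genes of antigen presentation on major histocompatibility complex class I rose in V79_8x: 14 of 17 against V79, and 0 of 17 in V79 against V21 (limma without the filter on dim genes). TAP1 and PSMB9, which the interferon list also holds, rose by +2.19 ± 0.11 and +2.12, and TAP2, PSMB8 and HLA-C by +1.37, +1.31 and +1.12. HLA genes are close copies, so their features can read each other's transcripts. PSMB10, PSME1 and NLRC5 did not pass (adjusted p = 0.87, 0.079 and 0.24). Of 6 genes that encode interferons, 0 rose against V79 or Mock, but IFNB1, IFNA2, IFNL1, IFNL3 and IFNG were below the filter on dim genes, so this says little about them. IFNB1 lay at 6.07, 5.97, 6.13 and 6.22 in Mock, V21, V79 and V79_8x, under the filter's limit of 6.43, and was called against V21 (+0.25 ± 0.05, adjusted p = 0.0058). The third list, 3 interferon-induced chemokines and the RNA sensor TLR3, had 4 of 4 up against V79 and 0 of 4 in V79 against V21. CXCL10 (adjusted p = 1.4e-11), CXCL11 and CCL5 rose from 6.13, 6.00 and 6.24, all under that limit, to 7.45, 7.03 and 6.99, so the size of these rises is uncertain, and TLR3 rose by +0.78 ± 0.10.

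One hypothesis was that V79 carries a smaller form of the V79_8x response, tested on genes called between the other 2 groups. These calls come from the fit of all 4 groups, so the tested arrays enter the spread behind them. Of 220 genes outside the interferon list that rose in V79_8x against Mock, 205 were higher in V79 than in V21, and their mean differed by 0.124 (9.806 ± 0.055 against 9.682 ± 0.068, exact permutation p = 0.0108, adjusted p = 0.0216). The 220 still hold interferon-stimulated genes, such as IFITM1, TAP2, PSMB8 and HLA-C (+5.35, +1.39, +1.31 and +1.14 against Mock), so the value is not free of that response. Of 291 such genes that rose in V79_8x against V21, 231 were higher in V79 than in Mock, and their mean differed by 0.076 (exact permutation p = 0.11). The first value is consistent with the hypothesis. The second missed the bound set for it. That bound was poorly chosen, since a p above 0.05 does not show that the groups did not differ. The interferon list, left out of these tests, was at 8.594 in Mock, 8.601 in V79 and 8.454 in V21. So interferon-response genes gave no sign of a smaller response in V79 against the vector, and their gap to V21 went with the lower V21. With genes called from a fit of only the other 2 groups, the differences were 0.128 (239 genes, 216 higher, exact p = 0.0152) and 0.0839 (177 genes, 139 higher, exact p = 0.104), although the choice of feature and the filter on dim genes still used all arrays. Genes that fell gave -0.11 (exact p = 0.00866, 73 genes) and -0.09 (exact p = 0.0433, adjusted p = 0.0577, 102 genes) in the same 2 comparisons. Without the 4 arrays that stand apart the rising genes gave 0.107 (exact p = 0.0238) and 0.0627 (exact p = 0.0317), and the falling genes -0.08 (exact p = 0.0159) and -0.09 (exact p = 0.0714). As the genes of a list move together on an array, a shared difference between cultures of the groups could give the same values, and repeat length was not separated from other differences between the plasmids.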
